A study of Arabidopsis thaliana with 9 samples.

How the data were processed

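Messenger RNA was sequenced from root tip sections of Arabidopsis thaliana seedlings in 9 samples, 3 for each of 3 lines: the trh1 mutant and transgenic lines labelled pPIN1::TRH1-YFP and pPIN2::TRH1-YFP. Per the labels' protocols, sections of about 1 mm were taken from seedlings grown upright on gelled medium with 1% sucrose for 2 to 6 days, RNA was treated with DNase on a column, and libraries were read on a BGISEQ-500 instrument. The labels call the samples biological replicates but do not give the age of each line, whether the lines were grown side by side or how many plants went into a sample. Per the submitters' processing notes, HISAT2 (version 2.0.4), Bowtie2, RSEM and DESeq2 were used with the TAIR10 build, in no stated order. Other settings of those steps, and whether counting used the strand, are not given in the sources used here.

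The authors deposited 1 table for each of the 3 pairs of lines. Each deposited table lists, per gene, an expression value for either line, a log2 fold change, a p-value and an adjusted p-value, a gene length and annotation terms. The deposited log2 values are the authors' own and are moderated, meaning that they are drawn toward 0 where a gene has few reads. The deposited adjusted p-values equal a Benjamini-Hochberg adjustment over every gene listed in that table. The deposited expression values are a signal scaled within the pair: their average is the mean of the size-factor-scaled reads of the 6 libraries, and their ratio is the moderated fold. They are therefore not plain means of a line, and they were not used as levels here. Genes with no read in either line of a pair are not listed.

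The design chosen before the data were examined read the authors' deposited log2 fold change and adjusted p for each gene, with a threshold of 0.05, because the tables hold no column per library. A gene called higher or lower passed that threshold. The p-values treat samples as biological replicates, as the labels state, and the smallest exact p of 3 samples against 3 would be 0.1. The tables, with 23074, 23045 and 23059 genes, were read as deposited. Where the deposited adjusted p is listed as 0, no value is printed.

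The deposited means carry about 15 digits, enough to work out the whole reads behind them. A mean over 6 libraries is a sum of whole numbers with fixed weights, and those weights were read from genes with a single read in all. Between 81 and 96 such genes marked each library. Lattice reduction then gave the whole reads of all 9 libraries for 23430 of 23430 genes, with a relative residual of at most 1e-14 against a tolerance of 2e-14. Whether these whole numbers are counted reads or rounded estimates of them is not given in the sources used here, so the word reads covers either. A library that entered both tables of a line belongs to that line. The solved libraries carry letters of no meaning, since no replicate number can be attached to them. Size factors computed anew from the solved reads differed by at most 3.7e-05 from the 18 read from single-read genes, a check of the solution against its own starting values, since no size factors are among the authors' columns. Solutions for the 137 genes with a mean above 30000 were not unique enough and were not used, which left 23293 genes. On simulated libraries, 100.00% of 23289 genes below that level were solved exactly, against 97.9% of the 141 genes above it.

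The solved totals lay between 33044109 and 35086311 reads per library, and size factors between 0.966 and 1.044. Levels are given as normalised reads, meaning solved reads divided by the library's size factor, as mean ± SD with n = 3. Where a line had no read of a gene, a bound was computed against a floor of 3 counts over the group. With 1 to 3 reads, the ratio carries an exact 95% counting interval. Reads without molecular identifiers are not independent molecules, so these limits cover counting error only, and they take the solved numbers as counted reads. Within a line, the chi-square per gene between libraries was 1.43 to 2.86, where sampling noise alone gives 1, so no pair of libraries looked like 1 library deposited again. These values also leave little spread between libraries of a line beyond sampling. The labels do not say whether samples of a line were grown separately, so the p-values may not cover variation between separate growths.

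After the data were seen, limma (version 3.58.1, R 4.3.3) with voom was added on the solved reads, for genes with at least 10 reads in at least 3 libraries, with all 9 libraries in 1 fit. It was tried on reads simulated from trh1 means with 1 common dispersion of 0.000384. Changes were planted in the pPIN1::TRH1-YFP libraries, only in genes with a trh1 mean of at least 20. There limma-voom recovered 78% of genes changed 1.2-fold, 86% at 1.5-fold, 98% at 2-fold and 100% at 4-fold. It gave 18 false calls among 18692 genes, beside 39, 43, 49 and 50 planted genes recovered at these folds. The false share of its calls in that run was thus above the threshold of 0.05. Recovery of genes with fewer reads or more spread was not tested. On the solved reads, limma-voom also gave the fits without each library in turn, a fit scaled to total reads, and the counts for other splits of the samples.

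21 gene lists with 333 genes were fixed before the data were examined, among them markers of root tissues and of stress. TRH1 is in none of them. A list's median deposited log2 fold change was set against 10000 random lists of the same size matched on mean level in 20 bins, two-sided, with adjustment over the lists of a comparison. The smallest p these permutations can give is 0.0002 before adjustment. Simulated lists of 12 genes with a mean above 20 were drawn in the comparison of trh1 with pPIN1::TRH1-YFP. Of these, 1.5% had an unadjusted p under 0.05 with nothing added, 93.5% with 0.20 added and 100% with 0.50 added. Lists with members of fewer reads, and p adjusted over the lists, were not tried there. Genes of a list can move together, which random lists ignore, so limma's camera test with an estimated inter-gene correlation was run beside it. Camera was also run with a preset correlation of 0.01. A call lost with the estimated correlation need not mean that members moved together. For gravitropism genes in pPIN1::TRH1-YFP against trh1 the estimate was -0.066, yet the unadjusted camera p rose from 0.0144 with the preset to 0.0432. Annotation terms of the tables with at least 10 genes were tested with a one-sided Fisher's exact test against all genes of the table. In that test's simulated run, random genes called 0 of 1385 terms.

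The genes named in the text follow a rule fixed beforehand. It took TRH1, the 12 largest changes in each direction among called genes in the upper 75% by mean level, up to 4 genes per list by smallest p, and the 5 smallest p, with equal p ordered by larger fold change. The rule's condition on library columns did not apply, as the tables hold none, but the solved libraries of every gene named for a large change did not overlap between the lines compared. Further members of lists are named where a count needs an example. Coordinates are those of the authors' tables on TAIR10, and the reference annotation gave equal starts and ends for 22910 of 22910 nuclear genes compared. Reads of near-identical genes, such as the small heat shock proteins of class I, the RBCS genes on chromosome 5, the LHCB1 genes and IMA1 and IMA2, can be divided between copies by the counting, so values of single members are uncertain. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, mpmath 1.4.1 and matplotlib 3.10.9 ran the other steps. Alternatives tried were an adjusted p of 0.01, a 2-fold minimum, genes in the upper 75% by mean level, voom with other filters and scalings, each library left out, other list statistics, other term sizes and another background.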

Results

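Root tips of the trh1 mutant of Arabidopsis thaliana were compared with those of transgenic lines labelled pPIN1::TRH1-YFP and pPIN2::TRH1-YFP. TRH1, also called KUP4, is a potassium transporter of the KUP/HAK/KT family that is needed for root hair growth and normal auxin distribution in the root. The labels name the transgenes by the promoters of PIN1 and PIN2, auxin efflux carriers made mainly in the stele and in the epidermis and cortex of the root tip, joined to TRH1 and yellow fluorescent protein. Each line had 3 samples, and totals were 33044109 to 35086311 reads per library. The study's title places TRH1 in auxin-dependent responses of the root system, and the comparisons ask how root tip transcripts differ when TRH1 is expressed from either promoter. No wild type was among the samples.

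TRH1 lies on chromosome 4 from 12320152 to 12324604 on the minus strand (TAIR10). It was nearly absent from trh1, with 4, 6 and 5 reads in the 3 libraries and a level of 4.96 ± 1.03 normalised reads (SD, n = 3). It reached 1960 ± 119 in pPIN1::TRH1-YFP and 11038 ± 101 in pPIN2::TRH1-YFP (SD, n = 3), 395-fold and 2226-fold the trh1 level. The pPIN2 line thus held 5.63-fold more TRH1 transcript than the pPIN1 line. Gene totals do not separate transgene reads from those of the mutant allele. The authors' deposited table gave log2 fold changes of 7.63 and 9.81 against trh1, moderated toward 0. The levels follow the labels in all 9 libraries.

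**Figure D1:**
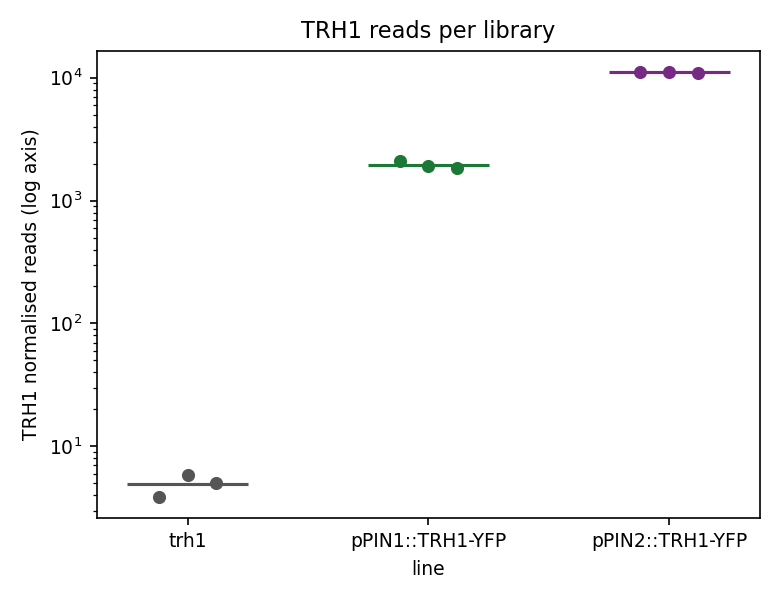
TRH1 normalised reads (log axis) in each of the 3 libraries of the 3 lines. Points are libraries and short lines are means (4.96, 1960 and 11038), and the lines do not overlap.

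The first comparison set pPIN1::TRH1-YFP against trh1. Its root tips held more transcript of small heat shock proteins, of genes that respond to iron shortage, of hypoxia genes and of the endodermal barrier. Of 12 heat shock genes, 11 rose and 0 fell, with a median log2 fold change of 1.34, and of 13 iron-deficiency genes 8 rose and 0 fell, with a median of 1.56. Among single genes, MRD1 fell from 145 ± 4.83 to 2.33 ± 3.19 normalised reads (SD, n = 3), and FSD1, an iron superoxide dismutase, fell from 13439 ± 162 to 5039 ± 92.9. In all, 4193 of 23074 genes passed the threshold in the authors' deposited table, 2571 higher and 1622 lower.

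Among called genes in the upper 75% by mean level, the largest rises behind TRH1 by the authors' deposited log2 fold change were IMS2 at 4.49, RALFL32 at 4.41, XTH31 at 4.37 and BHLH39 at 3.86. IMS2, a methylthioalkylmalate synthase of glucosinolate side chains, had 2 reads in all in trh1 and 282 in pPIN1::TRH1-YFP, 145-fold with a 95% counting interval of 39.4 to 1193. RALFL32, which encodes a small signalling peptide of the RALF family, had 0 reads in trh1 and 74.2 ± 13.4 normalised reads in the transgenic line, at least 74.8-fold higher against a floor of 3 counts over the group. XTH31, a xyloglucan-modifying enzyme of the cell wall, rose 40.9-fold. The next of these genes were AT2G14247 at 3.79, AT5G05250 at 3.59, the nicotianamine synthase NAS4 at 3.34, the isopropylmalate isomerase subunit IPMI1 at 3.26, the laccase LAC7 at 3.08, and IGMT3 at 2.93 in the deposited table. The cold-induced LTI78 rose from 50.8 ± 5.43 to 432 ± 9.55 normalised reads (SD, n = 3). The smallest deposited adjusted p belonged to FSD1, TT4, BGAL4, SAHH2 and EXT4. TT4, the chalcone synthase that opens flavonoid synthesis, rose from 4848 ± 140 to 17416 ± 366 normalised reads, and the extensin gene EXT4 from 1171 ± 25.9 to 4653 ± 359 (SD, n = 3).

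At the same levels, the largest falls after MRD1 were smaller. ASN1, a glutamine-dependent asparagine synthetase, fell by 2.34 on the log2 scale in the deposited table, and the MADS-box gene AGL42 fell by 1.71. AT4G23590, which lies on chromosome 4 close to TRH1, AT3G11420, AT3G24790, FSD1 and PRA1.F1 had deposited log2 values of -1.66, -1.51, -1.44, -1.42 and -1.35. AT2G33830, AT5G35940, AT5G42930 and AT5G53490 had deposited log2 values of -1.29, -1.25, -1.20 and -1.20. With each library left out in turn, limma-voom log2 fold changes of IMS2 lay between 6.00 and 6.78. MRD1 and AT2G14247 passed the read filter in only 3 fits each, at -7.37 to -5.51 and 4.09 to 6.02. Those fits left out libraries of the line with fewer reads of the gene, so libraries of the other line were not tried. Larger changes were mostly rises: among 479 genes changed at least 2-fold, 452 were higher and 27 lower.

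In the heat shock list, HSP23.6 rose from 346 ± 10.1 to 1113 ± 33.2 normalised reads, HSP17.4 from 384 ± 19.3 to 1164 ± 31.1, HSP17.6II from 533 ± 21.8 to 1406 ± 95.3 and HSP101 from 1693 ± 87.2 to 3635 ± 69.9 (SD, n = 3). HSP70 was the member that did not pass, with a deposited log2 fold change of 0.01. The list passed with an adjusted p of 0.00084, the smallest the permutations could give here, and 0.0063 with an estimated correlation, and 11 members rose when adjusted over the list alone. In the iron list, IRT1, the main root iron importer, rose 24.8-fold to 57.2 ± 3.03 normalised reads, and OPT3, a phloem iron transporter, from 196 ± 4.43 to 883 ± 52.4 (SD, n = 3). The transcription factor genes BHLH38 and BHLH39 had deposited log2 fold changes of 3.64 and 3.86 and the signalling peptide genes IMA1 and IMA2 of 2.80 and 2.92. FIT, the main regulator of iron uptake, lay at 0.04. The list passed with an adjusted p of 0.00084, and 0.0081 with an estimated correlation, and 8 members rose when adjusted over the list alone. By limma-voom, which does not draw folds toward 0, the list's median was 2.39. That median covers the 11 members past the read filter, against 13 in the deposited table, so the medians are not of the same genes.

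Of 10 hypoxia genes, 8 rose and 0 fell, with a median of 0.75 (adjusted p = 0.00084, and 0.012 with an estimated correlation). They included the fermentation genes ADH1 at 1.90 and PDC1 at 1.51 on the deposited log2 scale, the haemoglobin HB1 at 0.86 and HRE2 at 1.29, and 8 rose when adjusted over the list alone. Of 9 endodermis genes 7 rose and 0 fell, with a median of 0.35 (adjusted p = 0.00084, and 0.019 with an estimated correlation). CASP1, which builds the Casparian strip, rose from 4125 ± 164 to 7023 ± 520 normalised reads, and the peroxidase gene PER64 from 5521 ± 104 to 8537 ± 133 (SD, n = 3), and 7 rose when adjusted over the list alone. Deposited log2 values of CASP2 and CASP4 were 0.59 and 0.50.

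Root hair genes rose less. Of 29, 14 rose and 2 fell, with a median of 0.17 (adjusted p = 0.00084, and 0.019 with an estimated correlation), and 16 rose and 3 fell when adjusted over the list alone. XTH14, AHA7, RHS19 and PRP1 had deposited log2 fold changes of 0.56, 0.55, 0.54 and 0.48. Of 11 touch, wounding and early stress genes, 7 rose and 0 fell, with a median of 0.35 (adjusted p = 0.0031, and 0.019 with an estimated correlation), and 8 rose when adjusted over the list alone. ZAT10 stood at 1.56, TCH3 at 0.59, ZAT12 at 0.45 and WRKY33 at 0.35 in the deposited table.

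The next lists passed the permutation test but not the test with an estimated correlation. Of 34 auxin response genes, 8 rose and 1 fell, with a median of 0.15 (adjusted p = 0.011, and adjusted p = 0.23 with an estimated correlation). The auxin-conjugating enzyme gene GH3.2 rose from 24.8 ± 2.22 to 131 ± 7.01 normalised reads (SD, n = 3), while IAA8 had a deposited log2 fold change of -0.23, and 10 rose and 1 fell when adjusted over the list alone. Of 18 stele and vascular genes 6 rose and 0 fell, with a median of 0.25 (adjusted p = 0.0021, and adjusted p = 0.42 with an estimated correlation). SEOR1 stood at 0.94, CESA7 at 0.43, XCP1 at 0.37 and TMO5 at 0.35 as deposited, and 6 rose and 1 fell when adjusted over the list alone. Of 10 ethylene genes, 4 rose and 1 fell, with a median of 0.24 (adjusted p = 0.003, and adjusted p = 0.20 with an estimated correlation). The ethylene precursor synthase genes ACS11 and ACS2 stood at 1.40 and 0.66, ACO2 at 0.26 and EBF2 at -0.13 as deposited, with 4 higher and 1 lower adjusted over the list alone. Of 10 genes of gravitropism and statolith starch, 0 rose and 3 fell, with a median of -0.22 (adjusted p = 0.0051, and adjusted p = 0.13 with an estimated correlation). ARL2, PGM1 and ARG1 had deposited log2 fold changes of -0.24, -0.21 and -0.11, and 3 fell when adjusted over the list alone.

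The other lists did not pass. Of 28 potassium transport genes, 7 rose and 5 fell, with a median of -0.02 (adjusted p = 0.84), and 8 rose and 6 fell when adjusted over the list alone. SKOR, the channel that releases potassium into the xylem, rose from 58.0 ± 6.62 to 212 ± 8.71 normalised reads (SD, n = 3), while KUP6, KEA2 and CBL9 had deposited log2 fold changes of 0.41, 0.18 and -0.31. Of 23 auxin transport genes, 6 rose and 0 fell (adjusted p = 0.81), with the same count when adjusted over the list alone, among them PILS3 at 0.36, ABCB4 at 0.23, PIN1 at 0.18 and AUX1 at 0.10 as deposited. In auxin metabolism 0 of 13 genes rose and 1, YUC3, fell (adjusted p = 0.95), in epidermal patterning 0 of 9 rose and 1, EGL3, fell (adjusted p = 0.69), and in root cap 1 of 7, CEL5, rose (adjusted p = 0.17). In the stem cell niche 1 of 10 genes, SCR, rose (adjusted p = 0.69), and in cell division 2 of 24 rose and 2 fell (adjusted p = 0.10). Photosynthesis had 1 higher and 2 lower of 17 (adjusted p = 0.17), phosphate starvation 2 higher and 2 lower of 9 (adjusted p = 0.22), jasmonate 1 lower of 16 (adjusted p = 0.46) and cytokinin response 0 of 14 (adjusted p = 0.95). Adjusted over the list alone, root cap had 2 higher, phosphate starvation 4 higher and 2 lower, and jasmonate 0 lower, and the other counts of this group stayed as given.

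Among annotation terms, 164 of 1385 were enriched among higher genes and 8 among lower ones. Higher genes included 154 of 479 annotated with the cell wall, where 53.4 were expected (adjusted p = 1.2e-32, Fisher's exact test), 73 of 197 with the cytosolic ribosome (22.0 expected, adjusted p = 3.4e-19) and 44 of 85 with rRNA processing (9.47 expected, adjusted p = 5e-18). Lower genes included 9 of 19 with pectate lyase activity (1.34 expected, adjusted p = 0.00092). limma-voom on the solved reads called 6358 genes, 3474 higher and 2884 lower, and when scaled to total reads 2847 higher and 4281 lower, so the larger share changed side with the scaling. That scaling shifted the median gene by -0.036 on the log2 scale.

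The second comparison set pPIN2::TRH1-YFP against trh1. Root hair genes rose together here, hypoxia genes rose further, and heat shock genes fell. Of 29 root hair genes 22 rose and 0 fell, with a median of 0.67, while of 12 heat shock genes 0 rose and 11 fell, with a median of -1.85. The thalianol genes THAS1 and CYP708A2, which make a root triterpene, rose from 7.92 ± 2.59 to 148 ± 16.9 and from 22.1 ± 1.21 to 319 ± 22.1 normalised reads (SD, n = 3). In all, 3027 of 23045 genes passed in the authors' deposited table, 1820 higher and 1207 lower.

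Among called genes in the upper 75% by mean level, the largest deposited log2 fold changes behind TRH1 at 9.81 were THAS1 at 3.63, ADH1 at 3.61, CYP708A2 at 3.61, XTH31 at 3.08, CYP705A5 at 3.06 and FTM1 at 2.98. ADH1, the alcohol dehydrogenase of fermentation, rose from 16.8 ± 4.48 to 255 ± 16.7 normalised reads (SD, n = 3). Of these genes, the arabinogalactan protein gene FLA6 followed at 2.64, then AT1G34510 at 2.55, AT5G26080 at 2.48, AGD11 at 2.41 and AT1G72140 at 2.38 as deposited. The smallest adjusted p belonged to TRH1, HSP70, TT4, RHS19 and AGP30. TT4 rose to 13923 ± 240, RHS19, a root hair peroxidase, from 1734 ± 52.0 to 4967 ± 64.2, and AGP30, a root arabinogalactan protein, fell from 20028 ± 155 to 7559 ± 315 normalised reads (SD, n = 3).

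The largest falls at these levels included heat shock protein genes and MRD1. HSP17.6II fell from 533 ± 21.8 to 11.3 ± 2.76 normalised reads (SD, n = 3). HSP17.6A had a deposited log2 fold change of -4.61. ATHSP22.0 was 115-fold lower, with a 95% counting interval of 30.3 to 921, and MRD1 was 214-fold lower, with an interval of 60.2 to 1811. HSP17.4 stood at -3.87, HSP23.6 at -3.48, AT1G54050 at -2.95, AT2G29500 at -2.87, the galactinol synthase gene GolS1 at -2.30, AT1G07400 at -2.23, HSP70 at -2.03 and the heat shock factor gene AT-HSFA7B at -1.99 as deposited. With each library left out in turn, limma-voom log2 fold changes lay between -7.19 and -6.07 for ATHSP22.0 and -3.34 and -2.39 for GolS1, and were at least 2.51 for AGD11. MRD1 lay between -7.41 and -6.58 in 3 fits, which left out libraries of pPIN2::TRH1-YFP only. With a trh1 library left out, MRD1 missed the read filter. At least 2-fold changes numbered 357, of which 311 were higher and 46 lower.

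In the root hair list, XTH12 rose from 325 ± 5.79 to 1145 ± 7.01, the proline-rich protein gene PRP3 from 2995 ± 25.5 to 6857 ± 326, and XTH14 from 1373 ± 44.1 to 3151 ± 54.5 normalised reads (SD, n = 3). XTH26, XTH13 and PRP1 had deposited log2 fold changes of 2.03, 1.58 and 1.21, the expansin genes EXPA7 and EXPA18 of 0.67 and 0.77, and the root hair regulators RHD6 and RSL4 of 0.26 and 0.30. The list's adjusted p was 0.001, the smallest the permutations could give here, and 0.00069 with an estimated correlation, and 22 rose and 1 fell when adjusted over the list alone. In the heat shock list HSP101 fell from 1693 ± 87.2 to 526 ± 7.40, HSP90.1 from 4594 ± 50.4 to 2435 ± 57.7 and HSP70 from 4241 ± 79.0 to 1038 ± 49.1 normalised reads (SD, n = 3). That list passed with an adjusted p of 0.001, and 0.0011 with an estimated correlation, and 11 fell when adjusted over the list alone. Of 10 hypoxia genes, 9 rose and 0 fell, with a median of 1.18 (adjusted p = 0.001, and 0.0013 with an estimated correlation), and 9 rose when adjusted over the list alone. PDC1 stood at 1.60, SUS4 at 1.34 and LBD41 at 1.19 as deposited.

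The lists that follow passed the permutation test and lost their call with an estimated correlation. Of 34 auxin response genes 6 rose and 3 fell, with a median of 0.15 (adjusted p = 0.0017, and adjusted p = 0.47 with an estimated correlation), and 7 rose and 4 fell when adjusted over the list alone. GH3.2 stood at 1.82 and IAA28 at 0.29, against GH3.1 at -1.18 and IAA8 at -0.25, as deposited. Of 9 endodermis genes 5 rose and 1 fell, with a median of 0.16 (adjusted p = 0.0021, and adjusted p = 0.27 with an estimated correlation), and 5 rose and 2 fell adjusted over the list alone. CASP2, CASP1 and PER64 stood at 0.32, 0.24 and 0.22 and CASP5 at -0.31 as deposited. Of 9 phosphate starvation genes 5 rose and 1 fell, with a median of 0.22 (adjusted p = 0.019, and adjusted p = 0.13 with an estimated correlation), with the same count adjusted over the list alone. PAP17 stood at 1.34, SPX1 at 1.33, the phosphate transporter gene PHT1;1 at 0.38 and PPCK1 at -0.31 as deposited.

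Of 10 ethylene genes 3 rose and 1 fell, with a median of 0.14 (adjusted p = 0.032, and adjusted p = 0.28 with an estimated correlation), with the same count adjusted over the list alone, among them ACS2 at 0.59, ACO1 at 0.58, ACO2 at 0.19 and EBF2 at -0.12 as deposited. Photosynthesis genes, at low levels in these tips, had 0 higher and 2 lower of 17, with a median of -0.45 (adjusted p = 0.001, and adjusted p = 0.13 with an estimated correlation), and 3 lower adjusted over the list alone. RBCS1A, whose call was lost without 1 pPIN2::TRH1-YFP library (limma-voom adjusted p = 0.068), fell from 43.8 ± 5.26 to 22.8 ± 9.61 and LHCB4.1 from 205 ± 9.57 to 157 ± 7.32 normalised reads (SD, n = 3). Of 16 jasmonate genes 1 rose and 0 fell, with a median of -0.15 (adjusted p = 0.012, and adjusted p = 0.82 with an estimated correlation). The limma-voom median was -0.01 over only the 9 members past the read filter. AOC2 was the gene that rose, with 9.87 ± 3.25 and 26.8 ± 5.61 normalised reads (SD, n = 3), so count and deposited median differ in sign, and 1 rose adjusted over the list alone.

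The remaining lists did not pass. Iron deficiency had 3 higher and 0 lower of 13, IRT1, F6'H1 at 0.72 and OPT3 at 0.61 as deposited, with a median of 0.09 (adjusted p = 0.44), although it passed by the mean of the signed p statistic (adjusted p = 0.022), in the upper 75% by mean level (median 0.61, adjusted p = 0.0078) and by camera with the preset correlation (limma-voom median 0.63, adjusted p = 0.034). The list had an adjusted p = 0.13 with an estimated correlation. Camera used the 11 members past the read filter. IRT1 lay between 2.01 and 2.62 by limma-voom with each library left out. Potassium transport had 6 higher and 2 lower of 28 (adjusted p = 0.26), with KEA3 at 0.50, KUP6 at 0.28, NHX2 at -0.32 and KUP2 at -0.18 as deposited. Auxin transport had 3 higher and 3 lower of 23 (adjusted p = 0.72). PILS7, with 0 reads in trh1, was at least 11.1-fold higher, and WAG1, PIN2 and ABCB4 stood at -0.46, -0.13 and 0.17 as deposited. Cytokinin response had 3 higher and 0 lower of 14 (adjusted p = 0.073), ARR6 at 0.68, ARR3 at 0.52 and ARR4 at 0.17 as deposited, but passed in the upper 75% by mean level (adjusted p = 0.017) and by camera with the preset correlation (adjusted p = 0.034), and not with an estimated correlation (adjusted p = 0.28). Auxin metabolism had 1 lower of 12, TAA1 at -0.33 (adjusted p = 0.43), epidermal patterning 2 higher and 2 lower of 9 (adjusted p = 0.30), stele 3 higher and 1 lower of 18 (adjusted p = 0.68), cell division 1 higher and 1 lower of 24 (adjusted p = 0.94), and touch and early stress 2 higher and 1 lower of 11 (adjusted p = 0.19). Root cap had 0 calls among 7 genes (adjusted p = 0.68), gravitropism 0 among 10 (adjusted p = 0.19) and the stem cell niche 0 among 10 (adjusted p = 0.39). Adjusted over the list alone, the counts were 8 higher and 3 lower for potassium transport, 3 and 4 for auxin transport, 1 and 0 for cell division and 3 and 1 for touch, and the other counts of this group stayed as given.

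Of 1383 annotation terms, 75 were enriched among higher genes and 21 among lower ones. Higher genes held 34 of 78 annotated with plant-type cell wall organization (6.16 expected, adjusted p = 7.8e-15, Fisher's exact test), 39 of 111 with peroxidase activity (8.77 expected, adjusted p = 1.6e-13) and 14 of 38 with root hair elongation (adjusted p = 5.4e-05). Lower genes held 34 of 140 with response to heat (7.33 expected, adjusted p = 4.6e-11) and 7 of 12 with water transport (0.629 expected, adjusted p = 0.00023). limma-voom called 4667 genes, 2627 higher and 2040 lower, and scaled to total reads 2387 higher and 2498 lower.

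Changes of both transgenic lines against trh1 were then set side by side. Of 22689 genes listed in both tables, 1132 were higher in both lines and 662 lower in both. Independent lists of these sizes would share 206 and 86. TT4, XTH31, IMS2, GH3.2 and ADH1 were among those higher in both, and MRD1 and FSD1 among those lower in both. Another 90 genes were higher in pPIN1::TRH1-YFP and lower in pPIN2::TRH1-YFP, where 137 would fall by independence, and 39 the reverse (130 by independence). The comparisons share the trh1 libraries. All 9 libraries were therefore simulated unchanged from trh1 means, the trh1 libraries included, with the common dispersion of 0.000384. These gave 0 genes called by limma-voom in the same direction, against 1569 higher and 1240 lower observed. Genes with more spread and variation between growths were not simulated, so the simulations cannot show what shared controls would give with them. The covariance of the log2 fold changes was 0.0433 against 0.0039 simulated, a difference of 0.0394. Pearson's r across genes, which are not independent replicates, was 0.482 observed and 0.494 simulated, so r was no higher than in the simulations. The 3 trh1 libraries could not be divided into parts of at least 2, so no separate controls were available.

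**Figure D2:**
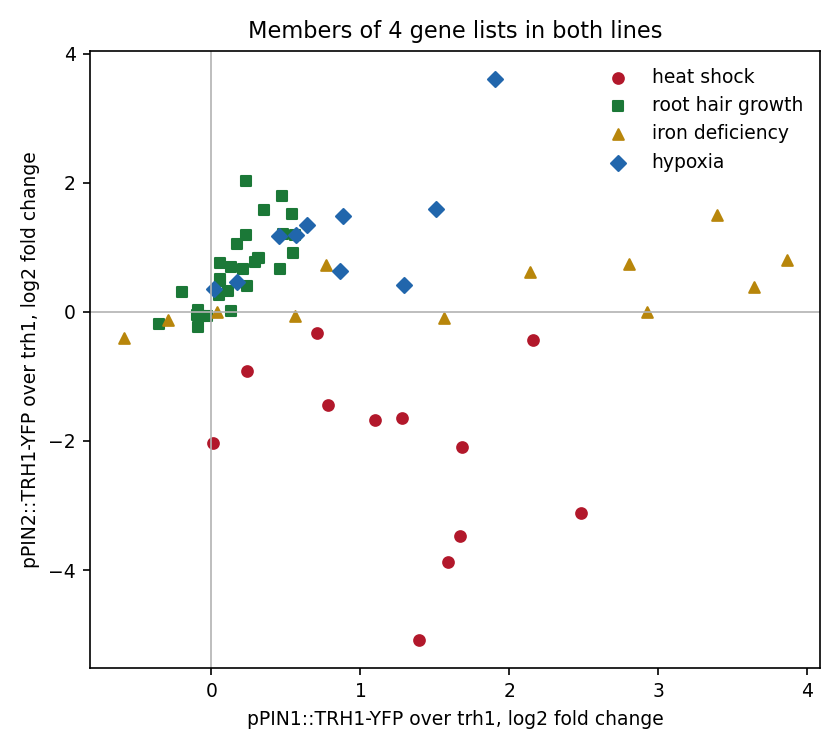
Deposited log2 fold change of each measured member of 4 gene lists, pPIN1::TRH1-YFP over trh1 on the x axis and pPIN2::TRH1-YFP over trh1 on the y axis. Heat shock genes lie right of 0 and below it, from HSP70 at 0.01 and -2.03 to HSP17.6II at 1.39 and -5.08, while most root hair and hypoxia genes lie above 0.

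The third comparison set pPIN2::TRH1-YFP against pPIN1::TRH1-YFP, lines that differ in promoter and in TRH1 level. The labels name no independent insertions of either construct, so insertion and line history cannot be told apart from promoter or level. Root hair genes were higher with pPIN2, and heat shock, iron-deficiency and endodermis genes were higher with pPIN1. Of 12 heat shock genes all 12 were lower in pPIN2::TRH1-YFP, with a median log2 fold change of -2.85, and of 29 root hair genes 22 were higher and 1 lower, with a median of 0.46. Of 14 iron-deficiency genes 0 were higher and 7 lower, with a median of -1.06. In all, 2389 of 23059 genes passed in the authors' deposited table, 1026 higher and 1363 lower in pPIN2::TRH1-YFP.

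HSP17.6II fell from 1406 ± 95.3 to 11.3 ± 2.76, HSP17.6A from 1334 ± 21.3 to 12.6 ± 2.24, HSP17.4 from 1164 ± 31.1 to 22.2 ± 0.809 and HSP101 from 3635 ± 69.9 to 526 ± 7.40 normalised reads (SD, n = 3). ATHSP22.0 was 757-fold lower, with a 95% counting interval of 201 to 6022. HSP21, a chloroplast heat shock protein, had 192 ± 22.1 normalised reads in pPIN1::TRH1-YFP and 0 reads in pPIN2::TRH1-YFP, at least 193-fold lower against a floor of 3 counts over the group. AT1G71000, HSP23.6, AT1G52560, AT1G54050, GolS1, APX2 and HSP15.7 had deposited log2 fold changes of -5.38, -5.12, -4.11, -4.02, -3.79, -3.76 and -3.76. By limma-voom with each library left out, ATHSP22.0 lay between -9.89 and -8.77, APX2 between -5.98 and -4.08 and GolS1 between -5.44 and -4.49. HSFA2, a heat shock factor, stood at -2.21, HSP17.6C at -2.92 and HSP70 at -2.03, and AT2G29500 and AT1G07400, among the smallest adjusted p, at -3.43 and -2.92 as deposited. The list's adjusted p was 0.0006, and 0.00029 with an estimated correlation, and 12 fell when adjusted over the list alone.

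Among called genes in the upper 75% by mean level, the largest rises after TRH1 at 2.49 were CYP94D1 at 2.42, FLA6 at 2.40, AT1G34510 at 2.35, ASN1 at 2.12, THAS1, CYP708A2 at 2.09 and AT2G05642 at 2.09 on the deposited log2 scale. AT3G28320 at 2.04, AT5G26080 at 1.96, AT1G63600 at 1.94 and the squalene epoxidase-like SQP2 at 1.91 followed among these genes. With each library left out, AT5G26080 lay between 2.00 and 2.62 and SQP2 at most at 2.71 by limma-voom. FLA6 rose from 74.1 ± 10.8 to 410 ± 17.1, THAS1 from 30.5 ± 9.16 to 148 ± 16.9 and ASN1 from 15.4 ± 4.49 to 82.8 ± 6.34 normalised reads (SD, n = 3). In the root hair list, RHS19 rose from 2525 ± 87.2 to 4967 ± 64.2, XTH12 from 451 ± 36.4 to 1145 ± 7.01, XTH14 from 2034 ± 53.4 to 3151 ± 54.5 and the peroxidase gene PER7 from 3472 ± 82.2 to 5002 ± 88.9 (SD, n = 3). It passed with an adjusted p of 0.0006, and 0.00029 with an estimated correlation, and 22 rose and 1 fell when adjusted over the list alone.

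In the iron list, BHLH39 fell from 211 ± 11.1 to 23.0 ± 1.69, BHLH38 from 49.9 ± 12.9 to 2.29 ± 1.43, IMA2 from 45.5 ± 2.45 to 2.99 ± 0.101 and OPT3 from 883 ± 52.4 to 303 ± 7.79 normalised reads (SD, n = 3; list adjusted p = 0.0006 by permutation, and 0.0042 with an estimated correlation), and 7 fell when adjusted over the list alone. By limma-voom the list's median was -1.98 over the 11 members past the read filter. BHLH38 lay between -4.64 and -3.88 in the 3 fits that kept it, each with a library of pPIN2::TRH1-YFP left out. Of 9 endodermis genes 0 rose and 7 fell, with a median of -0.26 (adjusted p = 0.0006, and 0.011 with an estimated correlation), and 7 fell when adjusted over the list alone. CASP1, PER64, CASP4 and CASP3 stood at -0.52, -0.40, -0.29 and -0.27 as deposited. Of 11 touch and early stress genes 0 rose and 4 fell, with a median of -0.27 (adjusted p = 0.001, and 0.015 with an estimated correlation), ZAT10 at -1.19, TCH4 at -0.64, TCH3 at -0.47 and TCH2 at -0.21 as deposited, and 8 fell when adjusted over the list alone.

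Hypoxia genes had 6 higher and 1 lower of 10, with a median of 0.47 (adjusted p = 0.0006, and 0.015 with an estimated correlation), and 6 higher and 2 lower adjusted over the list alone. ADH1 stood at 1.74, PCO2 at 0.73, SUS4 at 0.71 and LBD41 at 0.62 as deposited. Phosphate starvation genes had 4 higher and 0 lower of 9, with a median of 0.26 (adjusted p = 0.0006, and 0.016 with an estimated correlation), SPX1 at 0.98, PAP17 at 0.58, PHT1;1 at 0.28 and SQD2 at 0.26 as deposited, and 5 higher adjusted over the list alone.

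Photosynthesis genes had 0 higher and 5 lower of 17, with a median of -0.49 (adjusted p = 0.0006, and adjusted p = 0.21 with an estimated correlation), and 6 lower adjusted over the list alone. RBCS1A fell from 85.8 ± 10.6 to 22.8 ± 9.61 and LHCB1.3 from 103 ± 11.5 to 53.8 ± 16.7 normalised reads (SD, n = 3). With each library left out, RBCS1A lay between -2.27 and -1.60 by limma-voom. LHCB1.2 and RBCS2B stood at -1.01 and -1.24 as deposited, and among genes in the upper 75% by mean level the list's median was 0.12 (adjusted p = 0.42). Cytokinin response genes had 3 higher and 0 lower of 14, with a median of 0.14 (adjusted p = 0.025, and adjusted p = 0.26 with an estimated correlation), ARR3 at 0.54, ARR6 at 0.45 and ARR4 at 0.26 as deposited, with the same count adjusted over the list alone. Auxin response genes had 3 higher and 1 lower of 34, with a median of -0.07 (adjusted p = 0.038, and adjusted p = 0.44 with an estimated correlation). IAA31, IAA14 and IAA28 stood at 0.63, 0.26 and 0.15 and GH3.1 at -1.22 as deposited, so median and count differ in sign. The call of IAA14 was lost without 1 pPIN2::TRH1-YFP library (limma-voom adjusted p = 0.059), and the list's count was the same adjusted over the list alone. The stem cell niche list had 0 higher and 2 lower of 10, with a median of -0.10 (adjusted p = 0.038, and adjusted p = 0.21 with an estimated correlation), and 2 lower adjusted over the list alone. WOX5, a marker of the quiescent centre, fell from 27.6 ± 2.15 to 9.97 ± 2.08 normalised reads (SD, n = 3).

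Further lists did not pass. Auxin transport had 1 higher and 5 lower of 23 (adjusted p = 0.054), PILS5 at 0.43 and PILS3, WAG1 and PIN1 at -0.40, -0.40 and -0.20 as deposited, but passed in the upper 75% by mean level (median -0.07, adjusted p = 0.013). It did not pass by camera with the preset correlation (adjusted p = 0.067) or with an estimated correlation (adjusted p = 0.33). Potassium transport had 3 higher and 2 lower of 28 (adjusted p = 0.50), with SKOR falling from 212 ± 8.71 to 95.0 ± 5.33 normalised reads (SD, n = 3). Ethylene had 1 higher and 1 lower of 10 (adjusted p = 0.28), ACO1 at 0.36 and ACS11 at -1.02 as deposited. Jasmonate had 1 higher of 16, MYC2 at 0.72 (adjusted p = 0.52), auxin metabolism 1 lower of 13, TAA1 at -0.32 (adjusted p = 0.51), root cap 1 lower of 7, CEL5 at -0.38 (adjusted p = 0.27), gravitropism 1 higher of 10, PGM1 at 0.20 (adjusted p = 0.68), and cell division 2 higher and 2 lower of 24 (adjusted p = 0.18). Epidermal patterning had 0 calls among 9 genes (adjusted p = 0.95) and stele 0 among 18 (adjusted p = 0.096). Adjusted over the list alone, auxin transport had 1 higher and 6 lower, and the other counts of this group stayed as given.

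Of 1394 annotation terms, 29 were enriched among genes higher in pPIN2::TRH1-YFP and 125 among lower ones. The first held 21 of 76 genes of plant-type cell wall organization (3.38 expected, adjusted p = 1.3e-08, Fisher's exact test), 12 of 38 of root hair elongation (1.69 expected, adjusted p = 2e-05) and 9 of 30 of water channel activity (1.33 expected, adjusted p = 0.00047). Lower genes held 51 of 142 of response to heat (8.39 expected, adjusted p = 2.9e-24) and 55 of 197 of the cytosolic ribosome (11.6 expected, adjusted p = 2.8e-20). limma-voom called 3633 genes, 1609 higher and 2024 lower, and scaled to total reads 2141 higher and 1594 lower.

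**Figure D3:**
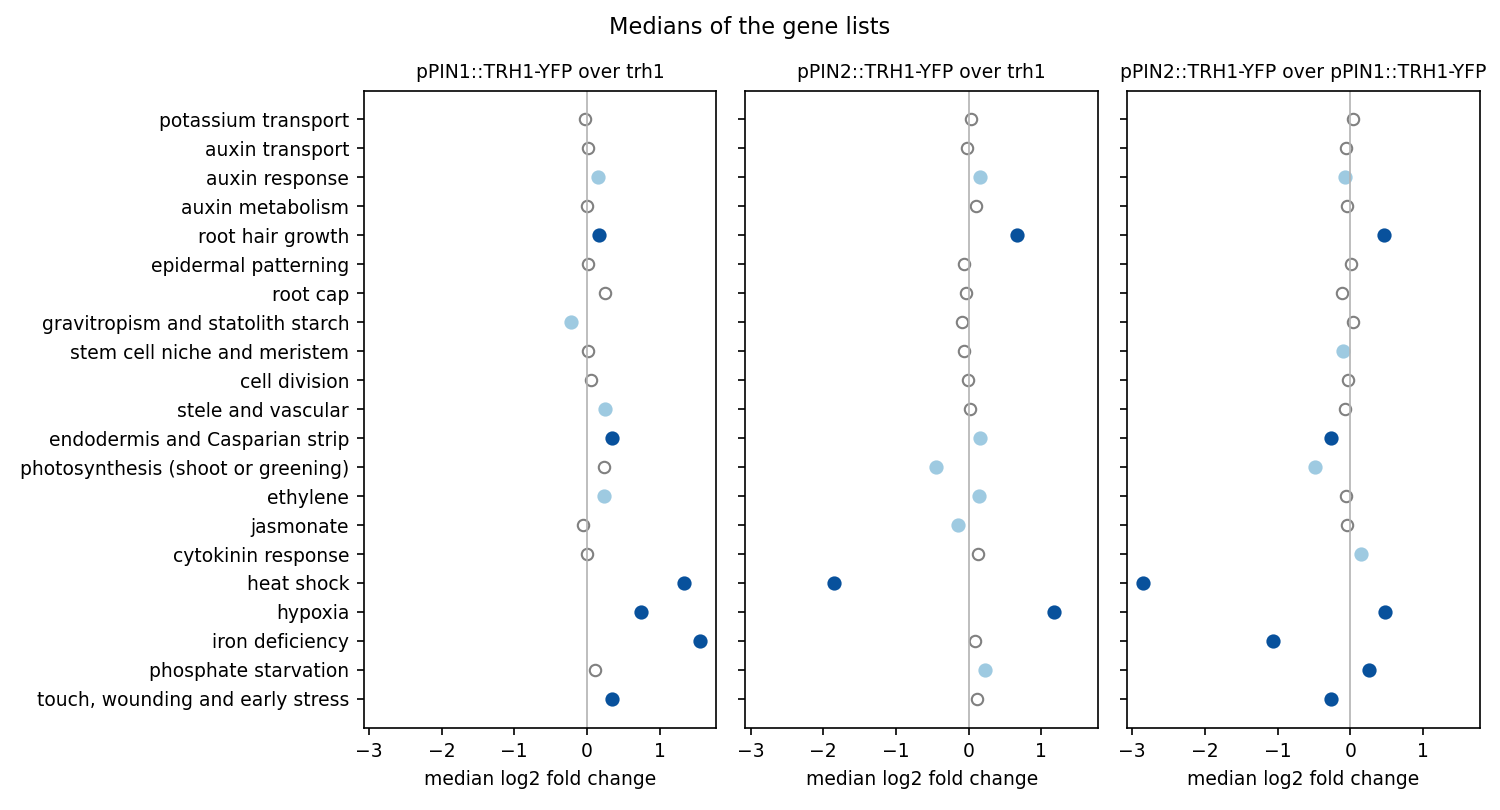
Median deposited log2 fold change of each of 21 gene lists in the 3 comparisons. Dark points passed the permutation test and the test with an estimated correlation, light blue points the permutation test but not the other, and open points neither. Heat shock stood at 1.34, -1.85 and -2.85 and root hair growth at 0.17, 0.67 and 0.46.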

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

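The tests in this part were chosen after the results were seen. The heat shock list moved in opposite directions in the transgenic lines relative to trh1, and the direct test between these lines drew attention to it. Its median log2 fold change was 1.34 in pPIN1::TRH1-YFP and -1.85 in pPIN2::TRH1-YFP against trh1, and -2.85 between the lines (adjusted p = 0.0006). Among single genes with deposited changes called in opposite directions and between the lines, the values of pPIN2::TRH1-YFP over pPIN1::TRH1-YFP were -6.38 for HSP17.6II, -6.30 for ATHSP22.0, -6.21 for HSP17.6A, -5.42 for HSP17.4, -5.38 for AT1G71000, -5.31 for HSP21 and -5.12 for HSP23.6. They were -4.11 for AT1G52560, -4.02 for AT1G54050, -3.79 for GolS1, -3.76 for APX2, -3.76 for HSP15.7, -3.07 for AT-HSFA7B, -2.92 for HSP17.6C and -2.77 for HSP101. Of 129 genes with such opposite changes, 21 changed at least 2-fold both ways, and 14 of these are annotated with response to heat.

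The heat shock pattern held under either scaling of the libraries. The limma-voom median between the lines was -3.10 with the usual scaling and -3.08 with libraries scaled to total reads. These scalings differed by 0.022 on the log2 scale for the median gene. Changing between them could not have removed the pattern, and other scalings were not tested. TRH1 transcript level alone stays open: the medians of 1.34 with less TRH1 and -1.85 with more restate the pattern, and a response that turns with the level cannot be told apart from one to the promoter. Growth or collection that differed between lines cannot be told apart from an effect of the transgenes: 11 of 12 genes had libraries that lay apart in the order pPIN2, trh1, pPIN1, but the labels give no growth batch and every library of a line shares its line. Heat shock transcripts respond within minutes to warmth and handling, so a difference of that kind could give this pattern. An effect of the promoter stays open as a biological hypothesis, and insertion or history of a line cannot be told apart from it.

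Root hair genes were above trh1 in both transgenic lines and highest in pPIN2::TRH1-YFP. More mature tissue in the pPIN2::TRH1-YFP sections than in the pPIN1::TRH1-YFP sections predicts a higher endodermis list, which differed by -0.26 between them. That list was also raised in pPIN1::TRH1-YFP against trh1 (median 0.35, adjusted p = 0.00084 by permutation). The difference may thus lie in a rise in pPIN1::TRH1-YFP, so a difference in maturity could not be ruled in or out. In pPIN2::TRH1-YFP against trh1 the endodermis list stood at 0.16 (adjusted p = 0.27 with an estimated correlation). More mature tissue relative to the trh1 sections could also not be ruled in or out. TRH1 transcript level alone cannot be told apart from the place of expression, because promoter and level change together (median 0.46 between the lines). TRH1 action in the epidermis, where the PIN2 promoter is active, remains a hypothesis.

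Iron-deficiency genes were highest in pPIN1::TRH1-YFP. The limma-voom median against trh1 was 2.39 with the usual scaling and 2.35 with libraries scaled to total reads. These scalings differed by -0.036 for the median gene, so changing between them could not have removed this pattern either. TRH1 transcript level alone stays open, since the median of -1.06 between the lines restates the pattern. Less iron in root tips of pPIN1::TRH1-YFP could give the pattern: all 4 ferritin genes were lower there than in trh1. Only 2 of 4 were lower than in both other lines, and 3 of 4 were also lower in pPIN2::TRH1-YFP than in trh1. In pPIN2::TRH1-YFP against trh1 the iron list did not pass by permutation (adjusted p = 0.44) or with an estimated correlation (adjusted p = 0.13). It passed in the upper part of genes by mean level (adjusted p = 0.0078) and by the mean of the signed p statistic (adjusted p = 0.022). Camera with the preset correlation also called it (adjusted p = 0.034). The ferritin falls there were thus not shown to occur without a raised iron list. Less iron stays open, the ferritin values had been seen before the ferritin test was set, and iron was not measured.

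For the counts of changed genes by limma-voom on the groups compared, the splits of 3 samples against 3 number 10, too few for a share under 0.05. The real splits called 6124, 4532 and 3867 genes and the highest other split 0 in each comparison, so that 1 of 10 splits gave as many.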

How the results depend on the processing

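The alternatives with limma-voom on solved reads, the preset correlation and the other background were chosen after the data were seen, and the others before. No paired analysis was possible because the solved libraries carry no replicate number and the deposited tables hold no library columns. An edgeR fit was planned only for tables with library columns, so that fit, its normalization and tool alternatives and the pseudocount were not run. The replicate block and split controls were not run either, and the adjustment over every gene is the deposited one. Requiring 2-fold left 479, 357 and 335 changed genes in the order of the comparisons. limma-voom called 6358, 4667 and 3633, scaled to total reads 7128, 4885 and 3735, and with only the groups compared 3867 in the last, and the causes of these shifts were not tested. At an adjusted p under 0.01 the counts were 3014, 2150 and 1733. Leaving out each library in turn gave 5409 to 5865, 3789 to 4443 and 2875 to 3049 with 2 libraries left in that line.

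Of the lists past the permutation test, 10, 9 and 11, camera with an estimated correlation called 6, 3 and 7. Photosynthesis genes between the transgenic lines turned from a median of -0.49 to 0.12 (adjusted p = 0.42) among genes in the upper 75% by mean level, where fewer members were tested. Shared changes of both lines numbered 1794, against 138 at 2-fold and 2957 by limma-voom over 18890 genes. Enriched terms at 2-fold, where fewer genes entered, numbered 62 higher and 0 lower, 23 and 6, and 2 and 45. The narrower background left 2 lower terms in the first comparison. What lowered these numbers was not tested. For the named genes, limma-voom kept direction and side of the threshold in 293 of 321 values, with 28 newly past it. Leaving out libraries did so in 1801 of 1908, with 105 newly past it and 2 lost: RBCS1A in pPIN2::TRH1-YFP against trh1 (-0.65, adjusted p = 0.068) and IAA14 between the transgenic lines (0.20, adjusted p = 0.059). Fits in which a gene missed the read filter are not among the 1908. Depth limits genes with few reads, where deposited folds are drawn toward 0.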

Other observations

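The genes of this part were chosen after their values were seen, apart from those named earlier. Of 26 genes annotated with glucosinolate biosynthetic process, 13 were higher and 1 lower in pPIN1::TRH1-YFP than in trh1, where 2.90 higher were expected (adjusted p = 2.5e-05, Fisher's exact test), with a median of 0.33. In pPIN2::TRH1-YFP 11 were higher and 1 lower, where 2.05 higher were expected (adjusted p = 0.00013), with a median of 0.30. Of these genes, IMD1 had 39.2 ± 7.82 normalised reads in trh1, 289 ± 20.7 in pPIN1::TRH1-YFP and 134 ± 12.5 in pPIN2::TRH1-YFP, CYP79F2 21.5 ± 2.44, 168 ± 17.1 and 85.1 ± 12.4, and IPMI1 15.4 ± 6.86, 180 ± 2.34 and 89.9 ± 10.8, while AT2G43090 had 6217 ± 156, 6231 ± 49.1 and 6311 ± 104 (SD, n = 3). The thalianol genes THAS1, CYP708A2, CYP705A5 and AT5G47980 on chromosome 5 were compared too: 3 of 4 were higher in pPIN1::TRH1-YFP and 4 of 4 in pPIN2::TRH1-YFP than in trh1, and 4 of 4 were higher in pPIN2::TRH1-YFP than in pPIN1::TRH1-YFP.

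Of the superoxide dismutase genes, FSD1 had 13439 ± 162, 5039 ± 92.9 and 10177 ± 51.8 normalised reads in trh1, with the PIN1 promoter and with the PIN2 promoter, CSD1 4522 ± 163, 7507 ± 257 and 5770 ± 76.8 and CSD2 3504 ± 117, 4271 ± 14.1 and 3841 ± 72.8 (SD, n = 3). Of the ferritin genes, FER1 had 4303 ± 66.7, 2894 ± 180 and 2696 ± 61.2 and FER3 4065 ± 30.7, 3085 ± 25.9 and 3602 ± 76.8 (SD, n = 3).

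Some genes were near absent from 1 or more lines. MRD1 had 145 ± 4.83 normalised reads in trh1, 2.33 ± 3.19 in pPIN1::TRH1-YFP and 0.678 ± 0.587 in pPIN2::TRH1-YFP (SD, n = 3). RALFL32 had 5, 28 and 0 reads in the libraries of pPIN2::TRH1-YFP, so that 1 library carried most of them, and MRD1 had 6, 0 and 1 in those of pPIN1::TRH1-YFP. AT3G14700 had 25.6 ± 2.01 normalised reads in pPIN2::TRH1-YFP against 0.33 ± 0.572 in trh1 and 0 reads in pPIN1::TRH1-YFP (SD, n = 3). Of the neighbours of TRH1, BTI1 had 10346 ± 165, 10482 ± 142 and 10336 ± 143 normalised reads in the same order of lines, and AT4G23590 had 66.3 ± 10.2 in trh1 and 37.2 ± 7.56 in pPIN2::TRH1-YFP (SD, n = 3). The first 2 principal components of the solved libraries held 42.6% and 34.1% of the variance, and the third held 5.1%, with values of -12.81 and 10.41 for 2 libraries of pPIN2::TRH1-YFP.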
